A study of Mus musculus with 56 samples.

How the data were processed

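Small RNA was sequenced from jejunal epithelial cells of female Sox9-EGFP mice on a C57BL/6J background. Per the labels' protocols, the mice were germfree, germfree littermates gavaged with faecal slurry for 2 weeks, or conventionally raised, and cells positive for Annexin-V, CD31, CD45 or Sytox-blue were gated out before sorting by EGFP. RNA was isolated with Norgen kits, about 50 ng went into TriLink CleanTag libraries, and single-end reads came from a HiSeq2000. Per the submitters' processing notes, the authors trimmed adapters with cutadapt and aligned with Bowtie to mm9, with versions not given in the sources used here. Per the series' design text, miRNAs and isomiRs were counted by the authors' own method and those under 100 RPM were left out. The deposited values are RPM of reads mapped to miRNAs (RPMMM) made by the authors.

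The deposited table holds 235 sequences, 162 canonical and 73 isomiR, of 153 mature miRNAs. Library totals were checked and run from 992008 to 997962 RPMMM, so the table holds nearly all of each library's miRNA share. Values are fractional and whole reads were not recovered, so count models were not used and the depth of each library is unknown. The smallest value above 0 in a library, 1.71 to 41.7 RPMMM, gives a rough idea of the precision, and a median of 2 sequences per library were at 0. Reads shared between near-identical miRNAs, such as locus copies and let-7 members, seem split by the authors' counting, so copies of one mature miRNA are not independent. Of 56 samples described, 55 have values, and the remaining one (GF315, non-sorted) is labelled as an alignment failure. No libraries had identical values, and correlations between libraries of one group ran from 0.691 to 0.994. Genome coordinates were not used here.

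Groups follow the labels for condition and population, and the littermate pair is also a label. The pairing was checked on the values: after group means were removed, littermate libraries correlated at 0.219, -0.0514, 0.158 and 0.356 in pairs A, B, C and D. Levels were analysed as log2(RPMMM + 1) with limma 3.58.1 in R 4.3.3, keeping sequences with a mean of at least 100 RPMMM in at least 1 group of the fit. The germfree and conventionalized libraries were fitted together with group means, the littermate pair as a fixed term and the mouse as a random block by duplicateCorrelation (estimated correlation 0.121). The conventionally-raised libraries were fitted alone (0.0617) for the population comparisons and with all others, without the pair term, for comparisons between conditions (0.137). P-values come from eBayes with a trend and were adjusted by Benjamini-Hochberg over the sequences tested in a comparison, with a threshold of 0.05. Errors on log2 values are limma standard errors, and the pseudocount makes the fold of low miRNAs smaller than the ratio of their means. Each population was compared with the mean of the other 3 sorted populations, non-sorted cells with the mean of all 4, conventionalized with germfree cells in each population and on average, and the difference in that response between Low and the mean of the others and by an F test over all 4.

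Lists of miRNAs were written from background knowledge: enteroendocrine, enterocyte, miR-17-92 and paralogues, crypt, let-7, epithelial (the miR-200 family with miR-203 and miR-205) and inflammation miRNAs, and markers of leukocytes, erythroid cells, mesenchyme, endothelium, liver and pancreas, the Dlk1-Dio3 cluster and the miR-34 family. A list member is the canonical sequence of that mature miRNA, older names were matched through a fixed table of aliases, and of locus copies the one with the highest mean level was used, a rule added after the design was set. A list with at least 3 members was tested by camera on the moderated t values with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also adjusted over the list alone. Named miRNAs are, per comparison, the 10 largest rises and the 10 largest falls among those past the threshold, with fewer than 3 calls also the 3 smallest p-values, members of the fixed lists, and always miR-375-3p, miR-192-5p and miR-194-5p. The design, lists, naming rule and other settings were set before the data were examined.

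The other settings were a pseudocount of 0.1 or 10, no filter, a filter of 1000 RPMMM, median-of-ratios scaling, quantile normalization, eBayes without a trend, limma array weights, no replicate block, each mouse left out in turn, each of the September and October groups alone, a separate fit per population with the littermate pair as block, sorted libraries only, and for lists the estimated correlation and all sequences of a mature miRNA. The pipeline was tested on simulated data for the comparison of CV and GF mice in Low, with 60 of 207 sequences changed in 20 simulations. It called 31.0% of sequences changed by log2 1, 54.0% at 1.5, 74.3% at 2 and 92.7% at 3, so changes near log2 1 were often missed, and 3.61% of the calls were unchanged sequences. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.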

Results

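The data are small RNA sequencing levels of 235 miRNA sequences in 55 libraries of jejunal epithelial cells from female Sox9-EGFP mice. Germfree (GF) mice, littermates conventionalized (CV) for 2 weeks with faecal slurry, and conventionally-raised (CR) mice contributed cells sorted by EGFP into High, Low, Sublow and Neg populations, and non-sorted (NS) cells. By the usual reading of this reporter, High is enriched for enteroendocrine cells, Low for crypt-base stem cells, Sublow for transit-amplifying progenitors and Neg for mature enterocytes and other differentiated cells. Each of High, Low and Neg has 4 mice per condition, Sublow has 3 GF, 4 CV and 3 CR mice, and NS has 3 mice per condition. Levels are RPMMM, reads scaled within each library to its miRNA total, the number of reads behind them is unknown, and 73 of the sequences are isomiRs with a shifted 5' end, written with the shift after the name. The 18 pairs of littermate libraries resembled each other slightly more than libraries of different litters (mean correlation of deviations 0.161 against -0.0563), and litter was a term of the CV and GF fit. Pairs A and B were sequenced in September, pairs C and D in October, and the CR mice in August at 28 to 29 weeks of age rather than 10 to 12.

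miR-215-5p, a p53-responsive miRNA of differentiated intestinal epithelium, dominated the Neg libraries, where it took 39.1% ± 15.5 (SD) of the reads in GF mice (n = 4), 39.6% ± 3.37 in CV mice (n = 4) and 44.9% ± 4.61 in CR mice (n = 4). Its share was 3.88% ± 0.684 in High and 4.64% ± 0.942 in Low of GF mice (n = 4 each), and 16.8% ± 1.28 in Sublow (n = 3). The share left to other miRNAs is thus smaller in Neg, so counts of higher and lower miRNAs depend on the scaling and are given under 3 scalings below. miR-192-5p, which shares a seed with miR-215-5p, varied far less, from 89439.9 RPMMM in Neg to 122065 in Sublow (GF and CV means).

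miR-375-3p, a regulator of endocrine cell mass and hormone secretion, averaged 131872 ± 8637 RPMMM in High (SD, n = 8 GF and CV libraries), against 94412 ± 55197 in Low (n = 8), 39236 ± 31031 in Sublow (n = 7) and 1076 ± 589.9 in Neg (n = 8). In GF mice alone Low (135744) was not below High (129743). Its log2 level in High was 3.30 ± 0.25 (SE) above the mean of the other 3 populations (limma, adjusted p = 1.2e-11), higher in 8 of 8 mice, with 3.39 in the September and 3.18 in the October libraries. miR-7b-5p, enriched in endocrine and neural cells, was higher in High by 3.88 ± 0.44 (adjusted p = 1.3e-08, 8 of 8 mice). miR-182-5p, of a cluster prominent in sensory and neuroendocrine cells, was higher by 2.08 ± 0.16 (adjusted p = 1.2e-11, 8 of 8 mice, 2.02 in the September and 2.13 in the October libraries). miR-672-5p averaged 338 ± 108 RPMMM in High, 65.3 ± 42.9 in Low and 28.5 ± 19.0 in Sublow, and was listed at 0 in 6 of 8 Neg libraries. miR-1224-5p averaged 293 ± 111 in High, 291 ± 299 in Low, from 529 in GF and 52.3 in CV mice, and was listed at 0 in 8 of 8 Neg libraries. In Sublow it stood at 268 in CV246 and at 4.93 to 101 in the other 6 libraries. miR-139-3p (291 RPMMM), miR-92b-3p (263) and miR-7a-2-3p (565) were each higher in High by limma and listed at 0 in 7 of 8 Neg libraries. In the other direction, miR-194-1-5p fell by 2.13 ± 0.23 in High (adjusted p = 4.2e-09, lower in 8 of 8 mice) and miR-802-5p fell by 2.72 ± 0.37 (adjusted p = 2.4e-07, lower in 8 of 8).

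7 of 7 enteroendocrine miRNAs were higher (also adjusted over the list alone, median log2 2.66, adjusted p = 5.7e-06, adjusted p = 0.0013 with an estimated correlation), including miR-375-3p, miR-7b-5p and miR-182-5p. 6 of 9 enterocyte miRNAs were lower (also adjusted over the list alone, median log2 -1.79, adjusted p = 2.8e-05, adjusted p = 0.019 with an estimated correlation), among them miR-194-1-5p and miR-215-5p (-1.79). 6 of 12 miR-17-92 group miRNAs were lower (also adjusted over the list alone, median log2 -0.99, adjusted p = 0.011, adjusted p = 0.64 with an estimated correlation), including miR-20b-5p (-2.66) and miR-18a-5p (-2.47) of this proliferation cluster. 1 of 8 crypt miRNAs was higher and 5 lower (2 higher and 5 lower adjusted over the list alone, median log2 -0.64, adjusted p = 0.25). 5 of 7 inflammation miRNAs were higher and 2 lower (also adjusted over the list alone, median log2 1.16, adjusted p = 0.36). 7 of 9 epithelial miRNAs were higher and 1 lower (also adjusted over the list alone, median log2 0.76, adjusted p = 0.39). This list holds the miR-200 family, which maintains epithelial identity, with miR-203 and miR-205, and miR-203-3p was the lower one. miR-200a-3p was higher by 0.76 ± 0.18 in 8 of 8 mice. 3 of 9 let-7 miRNAs were higher (also adjusted over the list alone, median log2 0.34, adjusted p = 0.39), but that median turned to -0.04 under quantile normalization. Over all miRNAs, 120 of 207 sequences differed in High, 75 higher and 45 lower. Median-of-ratios scaling gave 70 higher and 55 lower, and quantile normalization 72 and 76. Median log2 was 0.32 without rescaling, 0.14 with median-of-ratios and 0.03 with quantile scaling. Within batches the counts were 78 higher and 63 lower in the September libraries and 51 and 20 in the October libraries.

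Low cells, the reporter's stem cell gate, shared several miRNAs with High in the pooled GF and CV mice. miR-375-3p was higher in Low by 2.35 ± 0.25 (SE, limma, adjusted p = 3.2e-08, 8 of 8 mice), with 1.93 in the September and 2.75 in the October libraries. miR-7b-5p was higher by 3.12 ± 0.44 (adjusted p = 1.3e-06, 8 of 8 mice), and let-7e-5p and miR-99b-5p, transcribed together with miR-125a, by 2.78 ± 0.40 and 2.64 ± 0.34 (adjusted p = 1.6e-06 and 2.7e-07, each in 8 of 8 mice). miR-125a-5p averaged 217 RPMMM in Low and 216 in High against 74.9 in Sublow, and was listed at 0 in 6 of 8 Neg libraries. miR-184-3p averaged 432 ± 316 RPMMM in Low, 479.9 ± 209 in High and 157 ± 116 in Sublow, though 147 in CV Low, and was listed at 0 in 6 of 8 Neg libraries. miR-194-1-5p fell by 1.58 ± 0.23 in Low (adjusted p = 1.6e-06, lower in 8 of 8 mice) and miR-215-5p fell by 1.40 ± 0.18 (adjusted p = 3.9e-07, lower in 7 of 8). 5 of 7 enteroendocrine miRNAs were higher (also adjusted over the list alone, median log2 1.98, adjusted p = 0.0060, adjusted p = 0.065 with an estimated correlation). 4 of 9 enterocyte miRNAs were lower (also adjusted over the list alone, median log2 -0.37, adjusted p = 2.5e-06, adjusted p = 0.010 with an estimated correlation). 7 of 9 let-7 miRNAs were higher (8 higher adjusted over the list alone, median log2 0.68, adjusted p = 0.26). 5 of 7 inflammation miRNAs were higher (also adjusted over the list alone, median log2 1.43, adjusted p = 0.081). 3 of 12 miR-17-92 group miRNAs were higher (2 higher adjusted over the list alone, median log2 0.47, adjusted p = 0.95), with a test pointing down although the median is positive. Quantile normalization turned that median to -0.03. 5 of 8 crypt miRNAs were higher and 1 lower (also adjusted over the list alone, median log2 0.52, adjusted p = 0.95), also with a test pointing down. 3 of 9 epithelial miRNAs were higher (also adjusted over the list alone, median log2 0.09, adjusted p = 0.87), namely miR-205-5p, miR-141-3p and miR-200c-3p, again with a test pointing down, and with medians of -0.26 and -0.30 under median-of-ratios and quantile scaling. Over all miRNAs, 100 sequences differed in Low, 85 higher and 15 lower. Median-of-ratios scaling gave 48 higher and 29 lower, and quantile normalization 39 and 39. Median log2 was 0.51 without rescaling, 0.17 with median-of-ratios and 0.04 with quantile scaling. Within batches the counts were 87 higher and 16 lower in the September libraries and 32 and 11 in the October libraries.

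miR-152-3p and miR-148a-3p were higher in Sublow progenitors, while miR-148b-3p did not pass (0.43 ± 0.19, adjusted p = 0.11). miR-152-3p averaged 98.7 ± 51.5 RPMMM in Sublow (n = 7) and 67.4 ± 50.8 in Low (n = 8) against 9.73 ± 7.87 in High and 7.78 ± 4.94 in Neg, higher than the other populations by 2.52 ± 0.48 (SE, limma, adjusted p = 6.2e-04, 7 of 7 mice). miR-148a-3p rose by 1.48 ± 0.13 (adjusted p = 1.2e-09, 7 of 7 mice), with 1.23 in the September and 1.78 in the October libraries. miR-21-5p, which is linked to growth and inflammation, was higher by 1.26 ± 0.23 (adjusted p = 5.5e-04, 6 of 7 mice), and miR-93-5p by 1.09 ± 0.23 (adjusted p = 0.0011, 7 of 7 mice). In the September and October libraries, miR-152-3p was higher by 1.52 and 3.70, miR-21-5p by 0.80 and 1.76, and miR-93-5p by 0.93 and 1.23. 4 of 12 miR-17-92 group miRNAs were higher (5 higher adjusted over the list alone, median log2 1.00, adjusted p = 0.042, adjusted p = 0.89 with an estimated correlation), including miR-92a-1-3p (1.24) and miR-25-3p (0.92). 4 of 8 crypt miRNAs were higher (5 higher adjusted over the list alone, median log2 0.70, adjusted p = 0.57). 2 of 7 inflammation miRNAs were higher (3 higher adjusted over the list alone, median log2 0.42, adjusted p = 0.57). 1 of 7 enteroendocrine miRNAs was higher (4 higher adjusted over the list alone, median log2 0.67, adjusted p = 0.78), namely miR-184-3p. Its mean in Sublow (157 RPMMM) was below those in High (480) and Low (432), and Neg stood at 0.895. A higher call in Sublow means above the mean of the other 3 populations, which Neg can draw down, and not the highest level. 1 of 9 enterocyte miRNAs was higher (3 higher adjusted over the list alone, median log2 0.41, adjusted p = 0.57). 2 of 9 let-7 miRNAs were higher (also adjusted over the list alone, median log2 0.35, adjusted p = 0.78), with a median of -0.02 under median-of-ratios scaling. 2 of 9 epithelial miRNAs were higher (also adjusted over the list alone, median log2 0.20, adjusted p = 0.57), namely miR-203-3p and miR-205-5p and none of the miR-200 family, with a test pointing down and medians of -0.17 and -0.09 under the other scalings. Over all miRNAs, 36 sequences were higher and 0 lower in Sublow by limma, with 70 at an unadjusted p under 0.05. Median-of-ratios scaling gave 7 higher and 4 lower, and quantile normalization 23 and 15, so the absence of lower sequences depends on the scaling. Median log2 was 0.40 without rescaling, 0.05 with median-of-ratios and 0.03 with quantile scaling. The Sublow count rested on few mice, with 65 in the September and 1 in the October libraries alone. It was 10 without GF244 or GF271, 23 without CV246, 20 without CV270 or CV304, 13 without CV314, 65 without GF305 and 64 without its Neg library alone. Leaving out any 1 mouse did not end the calls of miR-152-3p, miR-148a-3p, miR-21-5p, miR-93-5p, miR-92a-1-3p or miR-25-3p.

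Neg cells carried the enterocyte program. miR-215-5p averaged 392516 ± 103397 RPMMM in Neg (n = 8) and rose by 2.66 ± 0.18 over the other populations (SE, limma, adjusted p = 1.0e-13, 8 of 8 mice), with 2.83 in the September and 2.49 in the October libraries. miR-194-1-5p, which is cotranscribed with miR-215, averaged 124209 ± 42778 and rose by 3.30 ± 0.23 (adjusted p = 1.2e-13, 8 of 8 mice), and its passenger strand miR-194-1-3p by 3.64 ± 0.19. miR-375-3p dropped by 6.31 ± 0.25 in Neg (adjusted p = 8.1e-19, lower in 8 of 8 mice), with -6.23 in the September and -6.42 in the October libraries. miR-7b-5p averaged 42.7 ± 32.2 RPMMM and let-7e-5p 24.8 ± 20.7 in Neg, each at 0 in 1 of 8 libraries, against 14412 and 2280.3 in High. The GF305 Neg library had 96 sequences at 0 and none between 0 and 41.7 RPMMM, so a 0 there may hide a low level. miR-192-5p fell by 0.34 ± 0.11 in Neg (adjusted p = 0.0065, lower in 8 of 8 mice), but it was higher by 0.56 under median-of-ratios scaling, and its call was lost without GF315 (adjusted p = 0.062). 6 of 9 enterocyte miRNAs were higher and 2 lower (also adjusted over the list alone, median log2 2.05, adjusted p = 3.1e-06, adjusted p = 0.0058 with an estimated correlation). With median-of-ratios scaling 8 of these were higher and 0 lower. 7 of 7 enteroendocrine miRNAs were lower (also adjusted over the list alone, median log2 -5.68, adjusted p = 5.8e-06, adjusted p = 0.0020 with an estimated correlation). 9 of 9 let-7 miRNAs were lower (also adjusted over the list alone, median log2 -1.31, adjusted p = 0.28), with let-7b-5p lower in 7 of 8 mice (-1.73). Quantile normalization left 1 let-7 member higher and 3 lower. 1 of 9 epithelial miRNAs was higher and 8 lower (also adjusted over the list alone, median log2 -1.16, adjusted p = 0.84), with miR-200c-3p at -1.33 and miR-203-3p the higher one. Median-of-ratios scaling left 1 of this list higher and 3 lower. 2 of 12 miR-17-92 group miRNAs were higher and 3 lower (1 higher and 3 lower adjusted over the list alone, median log2 -0.33, adjusted p = 0.28), with a test pointing up. The other scalings turned that median to 0.51 (median-of-ratios) and 1.06 (quantile). 1 of 8 crypt miRNAs was higher and 4 lower (also adjusted over the list alone, median log2 -0.72, adjusted p = 0.53), also with a test pointing up and medians of 0.18 and 0.35 under these scalings. 5 of 7 inflammation miRNAs were lower (also adjusted over the list alone, median log2 -2.93, adjusted p = 0.11). Over all miRNAs, 157 sequences differed in Neg, 25 higher and 132 lower. Median-of-ratios scaling gave 48 higher and 77 lower, and quantile normalization 72 and 67, so the number of lower calls depends on the scaling. Median log2 was -1.19 without rescaling, -0.31 with median-of-ratios and -0.12 with quantile scaling. Within batches the counts were 43 higher and 126 lower in the September libraries and 18 and 115 in the October libraries.

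Non-sorted cells had higher levels of some blood cell markers, read singly, beside enterocyte miRNAs. miR-142-5p, a leukocyte miRNA, was higher in NS than in the sorted populations by 4.74 ± 0.79 (SE, limma, adjusted p = 1.5e-05, higher in 5 of 6 mice), with 5.38 in the September and 3.24 in the October libraries, averaging 69.8 ± 109.7 RPMMM in GF and 625 ± 686 in CV mice (n = 3 each). miR-486-5p, an erythroid miRNA, was higher by 2.92 ± 0.67 (adjusted p = 5.5e-04, 5 of 6 mice), mostly in the September libraries (4.01, against 0.72 in October). miR-143-3p, of mesenchyme and smooth muscle, was higher by 1.44 ± 0.32 (adjusted p = 4.1e-04, 1.75 in the September and 0.81 in the October libraries). miR-194-1-5p rose by 2.40 ± 0.26 (adjusted p = 1.4e-08, 6 of 6 mice). miR-375-3p fell by 2.17 ± 0.28 (adjusted p = 4.4e-07, lower in 6 of 6 mice), and miR-1224-5p averaged 1.08 RPMMM in NS. miR-146a-5p was higher by 1.42 ± 0.53 (adjusted p = 0.024), a call lost without GF271 (adjusted p = 0.24), CV246 (0.051), CV270 (0.059) or CV304 (0.062). 7 of 9 enterocyte miRNAs were higher and 1 lower (also adjusted over the list alone, median log2 1.44, adjusted p = 4.5e-06, adjusted p = 0.013 with an estimated correlation). 6 of 7 enteroendocrine miRNAs were lower (also adjusted over the list alone, median log2 -1.74, adjusted p = 0.0020, adjusted p = 0.034 with an estimated correlation). 3 of 12 miR-17-92 group miRNAs were higher and 1 lower (2 higher and 1 lower adjusted over the list alone, median log2 1.00, adjusted p = 0.14). 2 of 8 crypt miRNAs were higher (1 higher adjusted over the list alone, median log2 0.13, adjusted p = 0.32). 1 of 7 inflammation miRNAs was higher and 3 lower (2 higher and 3 lower adjusted over the list alone, median log2 -0.71, adjusted p = 0.66). 7 of 9 let-7 miRNAs were lower (also adjusted over the list alone, median log2 -0.94, adjusted p = 0.056). 1 of 9 epithelial miRNAs was higher and 5 lower (also adjusted over the list alone, median log2 -0.39, adjusted p = 0.66), miR-203-3p being the higher and miR-205-5p among the lower ones, and with median-of-ratios scaling 1 higher and 0 lower. Over all miRNAs, 115 sequences differed in NS, 38 higher and 77 lower. Median-of-ratios scaling gave 49 higher and 55 lower, and quantile normalization 61 and 71. Median log2 was -0.27 without rescaling, 0.06 with median-of-ratios and -0.07 with quantile scaling. Within batches the counts were 47 higher and 70 lower in the September libraries and 13 and 49 in the October libraries.

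**Figure D1:**
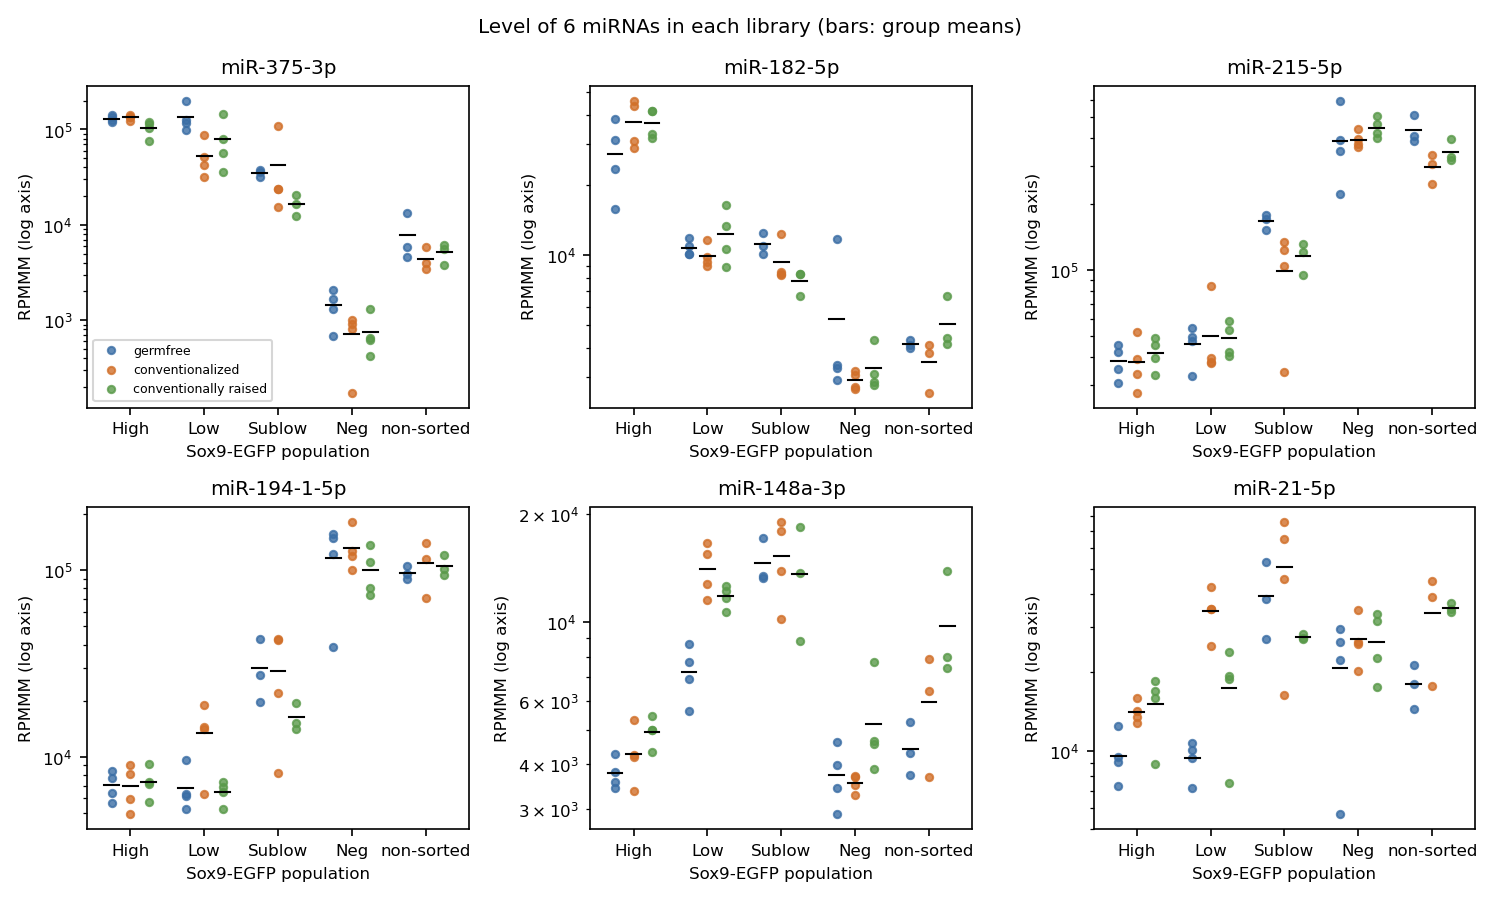
Levels of 6 miRNAs in every library by population and condition (RPMMM, log axis), with bars at group means. miR-375-3p is high in High and GF Low, miR-182-5p in High, and miR-215-5p and miR-194-1-5p in Neg and NS. Of the sorted populations, Sublow has the highest means of miR-148a-3p and miR-21-5p in each condition.

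The population comparisons were repeated in CR mice, sequenced in another run. In CR High, miR-375-3p was higher by 3.48 ± 0.29 (SE, limma, adjusted p = 8.2e-09, n = 4) and miR-182-5p by 2.46 ± 0.18 (adjusted p = 1.7e-09). In CR Neg, miR-194-1-5p rose by 3.43 ± 0.17 (adjusted p = 6.2e-13) and miR-375-3p dropped by 6.14 ± 0.29 (adjusted p = 5.1e-13), and miR-1224-5p, miR-672-5p and miR-184-3p were listed at 0 in 4 of 4 libraries. Across the 184 sequences tested in both sets, which are not independent replicates, the effects correlated at r = 0.974 in High, 0.873 in Low, 0.60 in Sublow and 0.972 in Neg. Of the higher calls, 63 were shared in High (27.8 for independent lists), 62 in Low (29.2), 24 in Sublow (11.8) and 22 in Neg (3.35). Of the lower calls, 33 were shared in High (8.04), 14 in Low (3.20) and 116 in Neg (80.9), and no sequence was called in opposite directions (0 by limma in each population).

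The lists were also tested between the CR populations. In CR High, 7 of 7 enteroendocrine miRNAs were higher (also adjusted over the list alone, adjusted p = 1.4e-05, adjusted p = 0.011 with an estimated correlation). 7 of 9 enterocyte miRNAs were lower (also adjusted over the list alone, adjusted p = 1.4e-05, adjusted p = 0.0096 with an estimated correlation). 5 of 10 miR-17-92 group miRNAs were lower (also adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.38 with an estimated correlation). In High the other lists did not pass as a whole (adjusted p from 0.080 to 0.70), with members higher and lower as follows: epithelial (7 and 1), let-7 (3 and 0), crypt (1 and 4, 2 and 5 adjusted over the list alone) and inflammation (3 and 2). In CR Low, 5 of 7 enteroendocrine miRNAs were higher (also adjusted over the list alone, adjusted p = 0.0040, adjusted p = 0.098 with an estimated correlation). 6 of 9 enterocyte miRNAs were lower (also adjusted over the list alone, adjusted p = 5.5e-04, adjusted p = 0.022 with an estimated correlation). 5 of 7 inflammation miRNAs were higher (also adjusted over the list alone, adjusted p = 0.054), and adjusted p = 0.022 with an estimated correlation. In Low the other lists did not pass as a whole (adjusted p from 0.41 to 0.83), with members higher and lower as follows: miR-17-92 (2 and 2), epithelial (1 and 4, 2 and 4 adjusted over the list alone), let-7 (5 and 0) and crypt (3 and 2, 4 and 2 adjusted over the list alone). In CR Sublow no list passed, and the epithelial list included a lower miR-200a-3p (-0.75), whose call was lost without CR180 (adjusted p = 0.072). In Sublow the 7 lists did not pass as a whole (adjusted p from 0.065 to 0.69), with members higher and lower as follows: enteroendocrine (0 and 1, 0 and 0 adjusted over the list alone), enterocyte (2 and 0), miR-17-92 (6 and 0, 7 and 0 adjusted over the list alone), epithelial (0 and 2, 0 and 1 adjusted over the list alone), let-7 (7 and 0), crypt (5 and 0, 5 and 1 adjusted over the list alone) and inflammation (0 and 0). In CR Neg, 7 of 7 enteroendocrine miRNAs were lower (also adjusted over the list alone, adjusted p = 7.1e-05, adjusted p = 0.026 with an estimated correlation). 7 of 9 enterocyte miRNAs were higher and 1 lower (also adjusted over the list alone, adjusted p = 1.6e-07, adjusted p = 6.5e-04 with an estimated correlation). In Neg the other lists did not pass as a whole (adjusted p from 0.21 to 0.98), with members higher and lower as follows: miR-17-92 (1 and 3), epithelial (1 and 7), let-7 (0 and 9), crypt (1 and 5) and inflammation (0 and 5). In High and Low miR-203-3p was among the lower members of the epithelial list, and in Neg it was the higher one. The median of this list in Neg was -0.96, but 0.03 under median-of-ratios scaling.

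In CR Sublow, miR-152-3p was under the filter (70.1 RPMMM) and miR-21-5p did not pass (0.61 ± 0.26, SE, limma, adjusted p = 0.068, n = 3). Other miRNAs marked it, among them miR-148a-3p, higher by 0.97 ± 0.22 (adjusted p = 0.0028), miR-92a-1-3p, higher by 1.90 ± 0.29 (adjusted p = 2.4e-04), and miR-17-5p, higher by 1.76 ± 0.56 (adjusted p = 0.017), the latter lost without CR180 (adjusted p = 0.066) or CR183 (0.11). miR-34a-5p, a p53 target, was higher by 1.76 ± 0.39 (adjusted p = 0.0026) in Sublow and fell by 2.04 ± 0.35 in High (adjusted p = 5.6e-05). In CR High, 77 higher and 39 lower sequences passed. Median-of-ratios scaling gave 60 higher and 59 lower, and quantile normalization 59 and 65. In CR Low, 73 higher and 43 lower passed. Median-of-ratios scaling gave 66 higher and 59 lower, and quantile normalization 56 and 66. In CR Sublow, 69 higher and 9 lower passed. Median-of-ratios scaling gave 32 higher and 27 lower, and quantile normalization 45 and 34. In CR Neg, 28 higher and 132 lower passed. Median-of-ratios scaling gave 63 higher and 76 lower, and quantile normalization 60 and 64. The median log2 in High was 0.38 without rescaling, 0.07 with median-of-ratios and -0.02 with quantile scaling. It was 0.12 without rescaling, -0.05 with median-of-ratios and -0.07 with quantile scaling in Low. The median log2 in Sublow was 0.42 without rescaling, -0.10 with median-of-ratios and 0.01 with quantile scaling. In Neg it was -1.04 without rescaling, -0.04 with median-of-ratios and -0.01 with quantile scaling. The Sublow count of 78 dropped to 33 without CR180 and 36 without CR183.

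**Figure D2:**
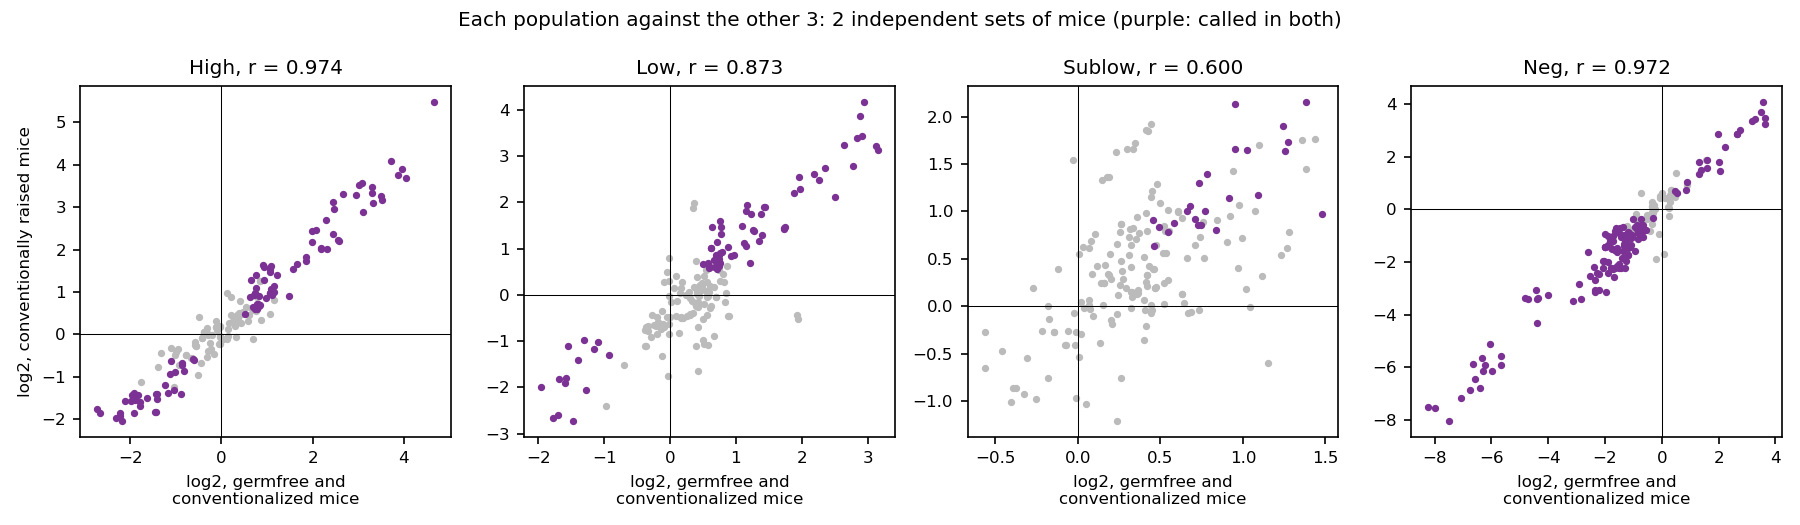
Log2 difference of each sorted population from the other 3, in GF and CV mice (x axis) against CR mice (y axis). Purple points passed the threshold in both sets.

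Low libraries differed between CV and GF mice. miR-25-3p and miR-93-5p, made from the miR-106b-25 cluster that promotes proliferation, rose from 4886 ± 1626 RPMMM in GF to 14141 ± 2061 in CV mice and from 1999 ± 794 RPMMM in GF to 8412 ± 2833 in CV mice (SD, n = 4 each), by log2 1.59 ± 0.25 and 2.13 ± 0.39 (SE, limma, adjusted p = 1.3e-04 and 2.7e-04, each higher in 4 of 4 pairs). miR-21-5p, which inflammation and growth signals induce, rose from 9337 ± 1549.7 RPMMM in GF to 34492 ± 7184 in CV mice, by 1.88 ± 0.40 (adjusted p = 0.0017, 4 of 4 pairs). miR-101b-3p and miR-107-3p rose by 1.92 ± 0.35 and 1.79 ± 0.32 (adjusted p = 2.7e-04 and 2.7e-04, 4 of 4 pairs each), and miR-203-3p, which restrains stemness in skin, by 1.60 ± 0.36 (adjusted p = 0.0029, 4 of 4 pairs). miR-34a-5p rose from 26.0 ± 13.1 RPMMM in GF to 212 ± 69.1 in CV mice, by 3.07 ± 0.88 (adjusted p = 0.016, 4 of 4 pairs), a call lost without CV304 (adjusted p = 0.083). miR-143-3p, a marker of mesenchyme and smooth muscle, rose by 2.13 ± 0.52 (adjusted p = 0.0049, 4 of 4 pairs). miR-802-5p rose by 2.24 ± 0.67 (adjusted p = 0.022), a call lost without GF244 (adjusted p = 0.069), GF315 (0.091), CV246 (0.060), CV304 (0.083) or CV314 (0.070).

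Other miRNAs fell in Low. miR-1224-5p fell from 529 ± 236 RPMMM in GF to 52.3 ± 23.3 in CV mice (SD, n = 4 each), by log2 -3.36 ± 0.75 (SE, limma, adjusted p = 0.0026, lower in 4 of 4 pairs), and miR-184-3p from 717 ± 122 RPMMM in GF to 147 ± 45.2 in CV mice, by -2.32 ± 0.58 (adjusted p = 0.0058, 4 of 4 pairs). miR-375-3p fell from 135744 ± 44599 RPMMM in GF to 53080.1 ± 23756 in CV mice, by -1.40 ± 0.47 (adjusted p = 0.042, 4 of 4 pairs), with -1.56 in the September and -1.25 in the October libraries. Its call was lost without GF244 (adjusted p = 0.060), GF271 (0.073), GF305 (0.070), GF315 (0.14), CV246 (0.10) or CV270 (0.083), and without the CV246 Low and Sublow libraries (0.058). miR-127-3p, of the imprinted Dlk1-Dio3 cluster, fell by 2.02 ± 0.64 (adjusted p = 0.031, 4 of 4 pairs), a call lost without GF271 (adjusted p = 0.099), GF315 (0.13) or CV314 (0.13). miR-192-5p (0.09 ± 0.20, adjusted p = 0.75, higher in 2 of 4 pairs) and miR-194-1-5p (0.91 ± 0.42, adjusted p = 0.13, 4 of 4 pairs) did not pass.

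Within each batch the direction of the leading Low miRNAs was the same. The log2 change was 1.15 in the September and 2.03 in the October libraries for miR-25-3p, 1.28 and 2.97 for miR-93-5p, 1.56 and 2.19 for miR-21-5p, 2.13 and 4.01 for miR-34a-5p, -2.63 and -4.09 for miR-1224-5p, and -1.86 and -2.79 for miR-184-3p. It was 1.43 and 2.42 for miR-101b-3p, 1.25 and 2.33 for miR-107-3p, 1.36 and 1.83 for miR-203-3p, 1.93 and 2.33 for miR-143-3p, 1.67 and 2.82 for miR-802-5p, and -1.46 and -2.58 for miR-127-3p. 3 of 12 miR-17-92 group miRNAs were higher (10 higher adjusted over the list alone, median log2 2.07, adjusted p = 6.0e-04, adjusted p = 0.45 with an estimated correlation), led by miR-25-3p and miR-93-5p. 4 of 8 crypt miRNAs were higher (also adjusted over the list alone, median log2 1.32, adjusted p = 0.024, adjusted p = 0.47 with an estimated correlation). They included miR-34a-5p, miR-130b-3p (1.13) and miR-221-3p (1.49). The miR-221-3p call was lost without CV304 (adjusted p = 0.061). 2 of 7 enteroendocrine miRNAs were lower (also adjusted over the list alone, median log2 -0.74, adjusted p = 0.0033, adjusted p = 0.091 with an estimated correlation), namely miR-375-3p and miR-184-3p. 2 of 9 enterocyte miRNAs were higher (also adjusted over the list alone, median log2 0.85, adjusted p = 0.25), namely miR-802-5p and miR-378-3p (1.23). 1 of 9 epithelial miRNAs was higher (2 higher and 1 lower adjusted over the list alone, median log2 0.35, adjusted p = 0.60), the one passing over all sequences being miR-203-3p, with a median of -0.05 under median-of-ratios scaling. None of 9 let-7 miRNAs passed (none adjusted over the list alone, median log2 0.17, adjusted p = 0.66), with a test pointing down and medians of -0.23 and -0.17 under median-of-ratios and quantile scaling. 1 of 7 inflammation miRNAs was higher (also adjusted over the list alone, median log2 -0.39, adjusted p = 0.43).

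In all, 27 of 207 sequences changed in Low, 23 higher and 4 lower, the higher ones being 18 canonical forms and 5 isomiRs of 19 mature miRNAs. Median-of-ratios scaling gave 19 higher and 24 lower, and quantile normalization 44 and 38. The median log2 was 0.36 without rescaling, -0.04 with median-of-ratios and 0.02 with quantile scaling, so the excess of rises depends on the scaling. Both rescalings called 21 of the 27, miR-25-3p, miR-93-5p, miR-21-5p, miR-34a-5p and miR-375-3p among them, but not miR-802-5p. Within batches the counts were 23 higher and 2 lower in the September libraries and 7 and 6 in the October libraries. Array weights gave 129 and a separate fit with the littermate pair as block 110. The count moved to 50 without mouse GF305, 17 without its Low library alone and 85 without its Neg library alone, which holds many zeros. 16 of the 27 calls, miR-25-3p, miR-93-5p and miR-21-5p included, were kept when each of the 8 mice was left out in turn.

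**Figure D3:**
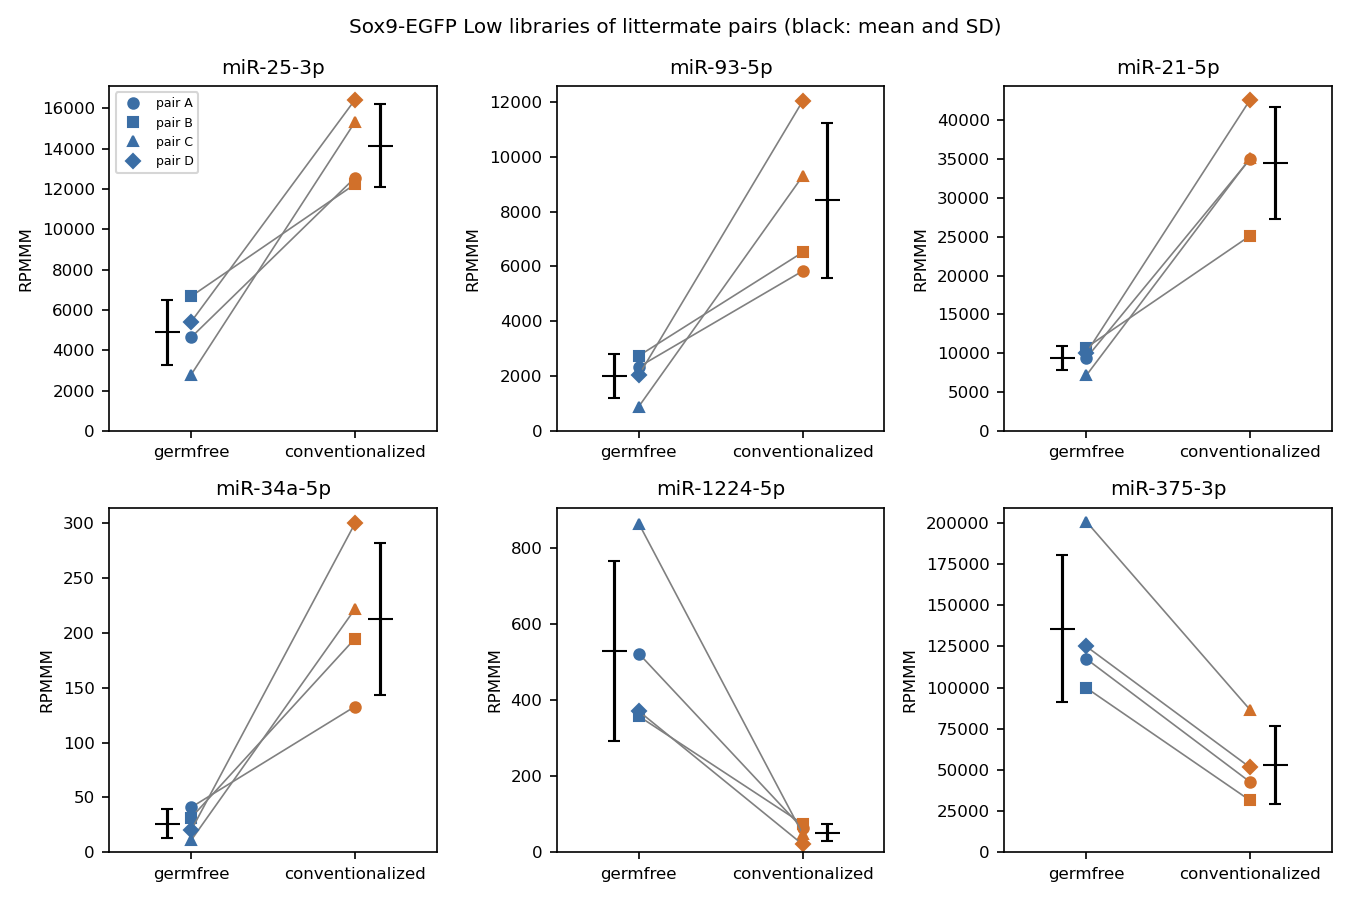
Levels (RPMMM, linear axis) of 6 miRNAs in Low cells of the 4 littermate pairs, GF and CV. Black marks give the mean and SD.

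The response of Low differed from that of the other sorted populations for some of these miRNAs. The CV minus GF change in Low exceeded the mean change in High, Sublow and Neg by log2 2.07 ± 0.57 (adjusted p = 0.022) for miR-143-3p, 1.64 ± 0.43 (adjusted p = 0.022) for miR-93-5p, 1.61 ± 0.38 (adjusted p = 0.0098) for miR-101b-3p, 1.39 ± 0.44 (adjusted p = 0.044) for miR-21-5p and 1.28 ± 0.27 (adjusted p = 0.0064) for miR-25-3p (SE, limma, n = 4 per group in Low). miR-1224-5p had a difference of -2.88 ± 0.82 (adjusted p = 0.025). The differences of miR-34a-5p (2.03 ± 0.96, adjusted p = 0.21), miR-802-5p (1.41 ± 0.73, adjusted p = 0.28), miR-375-3p (-0.96 ± 0.51, adjusted p = 0.28), miR-184-3p (-1.67 ± 0.63, adjusted p = 0.11) and miR-127-3p (-1.56 ± 0.69, adjusted p = 0.19) did not pass, so a change of theirs restricted to Low is not shown. In all, 17 sequences differed upward and 1 downward. The F test over all 4 populations called 0 by limma (smallest adjusted p = 0.053, 35 at an unadjusted p under 0.05), but 26 without GF305 and 3 without CV246, and 0 in either batch alone. It called 35 without the GF305 Neg library and 9 without the CV246 Low and Sublow libraries, and 104 with array weights. The response of High, Sublow or Neg against the others gave 0 sequences each by limma (5, 10 and 22 at an unadjusted p under 0.05). Its list tests passed only at the preset correlation, for enteroendocrine and miR-17-92 miRNAs in High (adjusted p = 0.016 and 0.016) and enterocyte miRNAs in Sublow (2.0e-04). In Low, 3 of 12 miR-17-92 group miRNAs were higher (also adjusted over the list alone, median log2 1.19, adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation). 2 of 8 crypt miRNAs were higher (3 higher adjusted over the list alone, median log2 0.87, adjusted p = 0.025, adjusted p = 0.42 with an estimated correlation). None of 7 enteroendocrine miRNAs passed (none adjusted over the list alone, median log2 -0.70, adjusted p = 0.025, adjusted p = 0.34 with an estimated correlation). 1 of 9 enterocyte miRNAs was higher (also adjusted over the list alone, median log2 0.88, adjusted p = 0.040, adjusted p = 0.42 with an estimated correlation). The other lists did not pass as a whole (adjusted p from 0.32 to 0.87), with members higher and lower as follows: let-7 (0 and 0), epithelial (1 and 0) and inflammation (1 and 0). The higher member of the epithelial list was miR-203-3p.

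**Figure D4:**
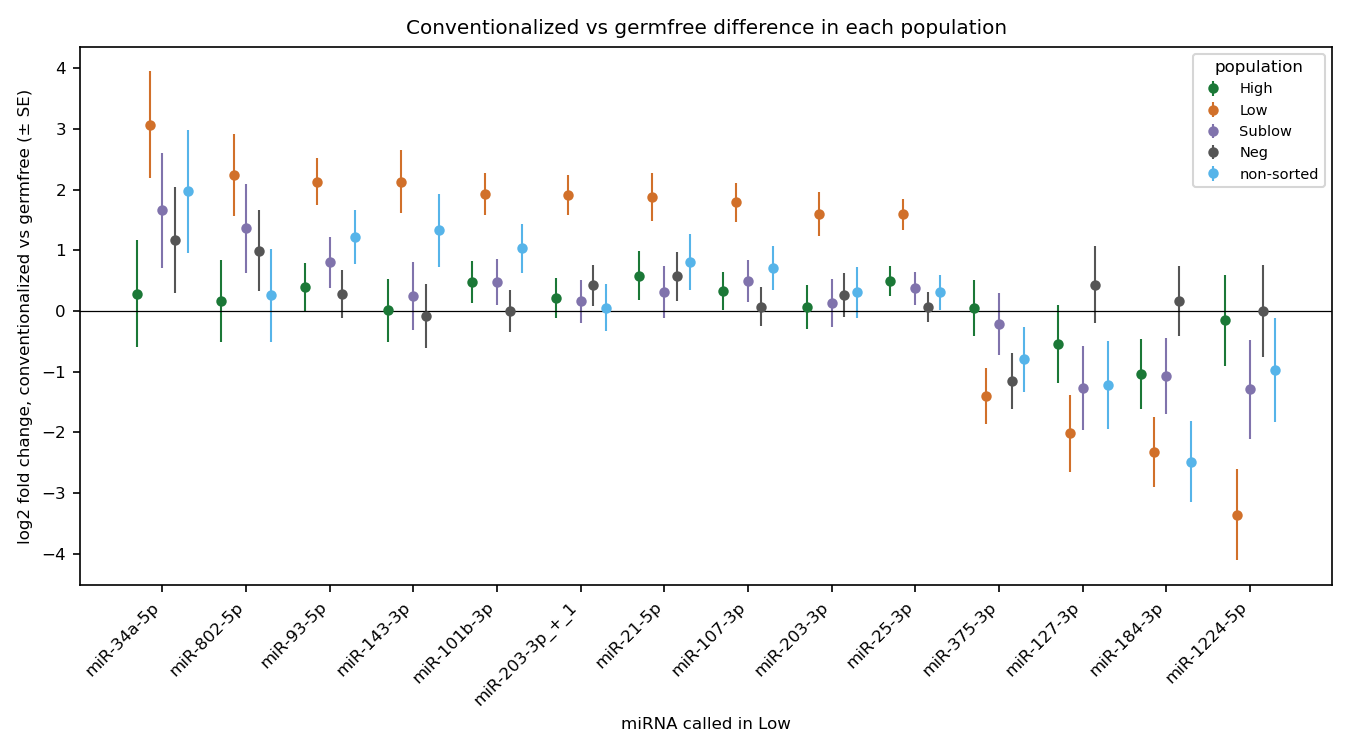
CV minus GF log2 change (SE) in each population for 14 miRNAs that changed in Low.

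In High, no miRNA passed the threshold for conventionalization (limma, 0 of 207, 2 at an unadjusted p under 0.05). miR-375-3p, at 129743 ± 9442 RPMMM in GF and 134000.0 ± 8534 in CV mice (SD, n = 4 each), differed by log2 0.05 ± 0.47 (SE, adjusted p = 0.99), and the smallest p belonged to miR-200a-5p (0.54 ± 0.22, adjusted p = 0.99). The lists gave no called member and no test past the threshold: the miR-17-92 group had a median of 0.31 (adjusted p = 0.092), the epithelial list 0.19 (0.092), let-7 -0.15 (0.19), crypt 0.09 (0.86), enteroendocrine -0.02 (0.35), enterocyte 0.09 (0.86) and inflammation miRNAs 0.18 (0.25), with 0 adjusted over the list alone (limma). The count was 0 in either batch alone and 9 with array weights.

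In Sublow, no single miRNA passed (limma, 0, 12 at an unadjusted p under 0.05). miR-215-5p was at 167419 ± 12738 RPMMM in GF (SD, n = 3) and 99382 ± 45112 in CV mice (n = 4), a log2 difference of -1.01 ± 0.36 (SE, adjusted p = 0.64, lower in 3 of 3 pairs), with -1.32 in the September and -0.77 in the October libraries. CV246 stood at 34257 and the other CV libraries at 105013 to 134730.0, and without mouse CV246 the difference was -0.56. miR-191-5p, an abundant housekeeping-type miRNA, differed by 0.70 ± 0.25 (adjusted p = 0.64). None of 12 miR-17-92 group miRNAs passed (none adjusted over the list alone, median log2 1.30, adjusted p = 0.0083, adjusted p = 0.42 with an estimated correlation). None of 9 enterocyte miRNAs passed (none adjusted over the list alone, median log2 -0.24, adjusted p = 0.018, adjusted p = 0.33 with an estimated correlation), and adjusted p = 0.25 under quantile normalization. The other lists, enteroendocrine, epithelial, crypt, let-7 and inflammation, did not pass as a whole (adjusted p from 0.052 to 0.90) or by any member, also adjusted over the list alone. The count was 0 in either batch alone, 66 with array weights and 1 with quantile normalization.

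In Neg, miR-375-3p was at 1431 ± 580.3 RPMMM in GF and 722 ± 374 in CV mice (SD, n = 4 each), a log2 difference of -1.15 ± 0.47 (SE, adjusted p = 0.34) that lay mostly in the October libraries (-2.16, against -0.14 in September). miR-181c-3p had the smallest p (1.92 ± 0.60, adjusted p = 0.34), and miR-215-5p differed by 0.10 ± 0.34 (adjusted p = 0.91). No miRNA passed (limma, 0, 28 at an unadjusted p under 0.05), 1 did without GF271, and the counts were 0 in the September and 1 in the October libraries, and 2 with array weights. The median log2 was 0.19 without rescaling, 0.33 with median-of-ratios and -0.01 with quantile scaling. No list passed either, with medians of 0.03 for enteroendocrine (adjusted p = 0.38), 0.08 for enterocyte (1.0), 1.18 for miR-17-92 (0.38), 0.29 for crypt (0.97), 0.03 for let-7 (0.83), 0.29 for epithelial (0.38) and 0.41 for inflammation miRNAs (0.68).

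In NS cells, the enteroendocrine list was lower in CV mice as a whole. None of 7 enteroendocrine miRNAs passed (1 lower adjusted over the list alone, median log2 -0.80, adjusted p = 4.5e-05, adjusted p = 0.0046 with an estimated correlation). miR-184-3p was at 26.6 ± 16.5 RPMMM in GF and 5.98 ± 6.14 in CV mice (SD, n = 3 each), a log2 difference of -2.48 ± 0.67 (SE, adjusted p = 0.11), and miR-375-3p differed by -0.80 ± 0.54 (adjusted p = 0.54). miR-142-5p was at 13.2, 196 and 0 RPMMM in the GF libraries and 372, 102 and 1402 in the CV libraries (4.85 ± 1.49, adjusted p = 0.13). No single miRNA passed (limma, 0, 34 at an unadjusted p under 0.05), against 1 in the September libraries, 4 without GF271, 1 without CV270 and 11 without the GF305 Neg library. No count is given for October, which holds only GF305 and CV304, both of pair C. The count was 50 with array weights, 6 with a pseudocount of 10 and 3 with either rescaling. The median log2 was 0.35 without rescaling, -0.19 with median-of-ratios and 0.03 with quantile scaling. None of 12 miR-17-92 group miRNAs passed (none adjusted over the list alone, median log2 1.15, adjusted p = 0.037, adjusted p = 0.63 with an estimated correlation). The other lists, enterocyte, crypt, let-7, epithelial and inflammation, did not pass as a whole (adjusted p from 0.085 to 0.63) or by any member, also adjusted over the list alone.

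Averaged over the sorted populations, miR-25-3p was the only miRNA past the threshold, higher in CV mice by log2 0.63 ± 0.15 (SE, limma, adjusted p = 0.043, n = 4 pairs). Its call was lost without GF244 (adjusted p = 0.23), GF305 (0.11), GF315 (0.058), CV246 (0.12) or CV304 (0.071), while the count was 17 without GF271, 8 without CV270, 39 without the GF305 Neg library, 12 without the CV246 Low and Sublow libraries and 0 without the GF305 Low library. It was 0 in either batch alone, 105 with array weights, 54 with quantile normalization and 0 with median-of-ratios scaling. miR-93-5p (0.90 ± 0.23), miR-181c-3p (1.30 ± 0.35) and miR-21-5p (0.84 ± 0.24) came close (adjusted p = 0.052 each), and miR-375-3p was at -0.68 ± 0.28 (adjusted p = 0.14). 1 of 12 miR-17-92 group miRNAs was higher (8 higher adjusted over the list alone, median log2 1.23, adjusted p = 3.6e-04, adjusted p = 0.41 with an estimated correlation). None of 7 enteroendocrine miRNAs passed (1 lower adjusted over the list alone, median log2 -0.33, adjusted p = 0.0030, adjusted p = 0.085 with an estimated correlation). The other lists did not pass as a whole (adjusted p from 0.099 to 0.96), with members higher and lower as follows: crypt (0 and 0, 4 and 0 adjusted over the list alone), epithelial (0 and 0, 2 and 0 adjusted over the list alone), enterocyte (0 and 0), let-7 (0 and 0) and inflammation (0 and 0, 1 and 0 adjusted over the list alone).

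Some sequences differed between CR mice and the CV and GF mice. miR-5099_-_2 was higher in CR than in CV mice by log2 2.54 ± 0.30 (SE, limma, adjusted p = 1.1e-08) and than in GF mice by 2.90 ± 0.30 (adjusted p = 3.2e-10), reaching 10784 ± 6912 RPMMM in CR Low (SD, n = 4) against 1893 ± 443 in CV Low. miR-21-5p_+_1 was higher than in CV by 2.00 ± 0.50 (adjusted p = 0.0035) and than in GF by 2.16 ± 0.50 (adjusted p = 0.0049), and miR-3096-5p by 2.04 ± 0.36 and 1.83 ± 0.37. miR-146a-5p, a feedback inhibitor of NF-kB signalling, was higher in CR than in GF mice by 1.58 ± 0.49 (adjusted p = 0.033), averaging 1079 ± 643 RPMMM in CR Low and 283 ± 89.2 in GF Low, and miR-25-3p by 0.52 ± 0.16 (adjusted p = 0.037). The miR-146a-5p call was lost without CR180 (adjusted p = 0.14), CR183 (0.15), CR243 (0.14), GF244 (0.056) or CV304 (0.053), and the miR-25-3p call without CR180 (adjusted p = 0.11), CR183 (0.17), CR243 (0.080), GF244 (0.075), GF305 (0.15) or CV304 (0.053). miR-143-3p fell by 0.90 ± 0.28 (adjusted p = 0.023) and miR-200c-3p fell by 0.55 ± 0.16 (adjusted p = 0.016) relative to CV mice. The first of these was lost without CR180 (adjusted p = 0.091), CR183 (0.077), CR242 (0.053), CV270 (0.071) or CV314 (0.094), and the second without CR180 (adjusted p = 0.053), CR183 (0.096) or CV246 (0.078). In all, 28 of 216 sequences differed from CV, 22 higher and 6 lower, 18 of the higher ones isomiRs. Median-of-ratios scaling gave 23 higher and 11 lower, and quantile normalization 28 and 30. Array weights gave 121. From GF, 17 differed, 16 higher and 1 lower, 9 of the higher ones isomiRs. Median-of-ratios scaling gave 19 higher and 6 lower, and quantile normalization 22 and 24. Array weights gave 85. These counts were 66 and 21 without GF305, 18 and 17 without CR242, 19 and 9 without CR180, 30 and 29 without CV270, 29 and 27 without CV246, 26 and 9 without GF244, 21 and 11 without CR183, and 21 and 11 without CR243. CR180 and CR183 share a littermate pair label, for which the fit has no term. Age, colony history and sequencing run differ together here, and their effects cannot be separated.

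Between CR and GF mice the enteroendocrine list passed only at the preset correlation. None of 7 enteroendocrine miRNAs passed (1 lower adjusted over the list alone, median log2 -0.41, adjusted p = 0.027, adjusted p = 0.27 with an estimated correlation). Against GF mice the other lists did not pass as a whole (adjusted p from 0.31 to 0.84), with members higher and lower as follows: epithelial (0 and 0), miR-17-92 (1 and 0), enterocyte (1 and 0), crypt (0 and 0), let-7 (0 and 0) and inflammation (1 and 0). Against CV mice the 7 lists did not pass as a whole (adjusted p from 0.056 to 0.88), with members higher and lower as follows: enteroendocrine (0 and 0), epithelial (0 and 1, 0 and 4 adjusted over the list alone), miR-17-92 (0 and 0), enterocyte (0 and 0), crypt (0 and 0), let-7 (0 and 0) and inflammation (1 and 0).

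Marker lists of other cells and tissues had few members in the table and were read by member. The leukocyte list (miR-142-5p and miR-146a-5p, the latter also on the inflammation list) had a median log2 of 0.37 in High, 0.83 in Low, 0.56 in Sublow, -1.76 in Neg and 3.08 in NS (GF and CV), and the erythroid miR-486-5p 1.78, -0.15, -0.27, -1.36 and 2.92. The mesenchyme marker miR-143-3p stood at -1.91, 0.45, 0.97, 0.49 and 1.44, and the endothelium list (miR-10a-5p and miR-139-5p) at 2.00, 0.67, 0.52, -3.19 and -1.48. miR-122-5p, for liver, stood at 0.06, 0.33, 0.86, -1.25 and -1.95, miR-127-3p of the Dlk1-Dio3 cluster at 151, 94.2, 52.9 and 0.288 RPMMM in High, Low, Sublow and Neg, and miR-34a-5p at log2 -2.19, 0.37, 1.36, 0.46 and 1.38. Between CV and GF mice in Low, the leukocyte list had a median of -0.17, miR-486-5p -0.45, the endothelium list 0.16 and miR-122-5p -1.39, without any member passing, while miR-143-3p, miR-127-3p and miR-34a-5p passed. Past the threshold in High were 1 leukocyte and 2 endothelium members, miR-486-5p and miR-127-3p upward and miR-143-3p and miR-34a-5p downward. In Low 1 leukocyte member, 1 endothelium member and miR-127-3p passed upward, and in Sublow miR-143-3p and miR-127-3p, with miR-34a-5p only over the list alone. The direction of miR-127-3p in Sublow turned under quantile normalization, and its mean there lay below High and Low. In Neg 1 leukocyte and 2 endothelium members, miR-486-5p, miR-127-3p and miR-122-5p passed downward, and in NS 2 leukocyte members, miR-486-5p, miR-143-3p and miR-34a-5p upward and 2 endothelium members, miR-127-3p and miR-122-5p downward. Over the list alone, 1 leukocyte member (list median 3.31) and miR-143-3p (1.33) were higher in CV than in GF NS cells, and miR-122-5p (2.40) in Sublow. None of these passed over all sequences (miR-143-3p in NS, limma, adjusted p = 0.26). miR-143-3p, miR-122-5p and miR-34a-5p are each the only member of their list in the table, so for them this is the unadjusted p. miR-122-5p averaged 79.8 ± 117 RPMMM (SD, n = 7) in Sublow.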

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

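The tests of cell mixture, library mix-up, share of reads, age or run, and zeros below were chosen only after the results were seen, while the splits of the samples were planned. In groups of 4 libraries, a library was singled out where its gap to the nearest other was a large part of the group's range. This was tried on 156 groups and found 17, and chance singles out about 1 in 20 groups. The share of the range taken by the gap follows each library. For levels it was computed on log2(RPMMM + 1), while the values beside it are in RPMMM.

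In GF Neg, library GF305 stood low for miR-21-5p (0.834, 5688 against 22287 to 29242 RPMMM), miR-25-3p (0.880, 1309 against 3291 to 3734 RPMMM) and miR-146a-5p (0.880, listed at 0), and high for sequences at 0 (0.831, 96 sequences). In CV Low, CV246 stood high for miR-215-5p (0.931, 84384 against 37712 to 39855 RPMMM) and its share of reads (0.954), and low for miR-146a-5p (0.851, 206 against 316 to 341 RPMMM), and its Sublow library stood high for miR-1224-5p (0.890, 268 against 4.93 to 8.03 RPMMM). Others were CR242 for miR-93-5p in High (low, 0.850, 1742 against 2173 to 2259 RPMMM) and miR-1224-5p in Low (high, 0.903, 1495 against 169 to 209 RPMMM), CV270 for miR-146a-5p in High (low, 0.915, 154 against 361 to 391 RPMMM), CV314 for miR-375-3p in Neg (low, 0.879, 172 against 807 to 996 RPMMM), GF305 for miR-34a-5p in High (low, 0.841, 9.62 against 17.4 to 19.4 RPMMM) and GF271 for miR-5099_-_2 in High (low, 0.951, 155 against 298 to 309 RPMMM). miR-184-3p was above 0 in Neg only in CV270 of the CV mice (4.61 RPMMM, a share of 1) and GF244 of the GF mice (2.55 RPMMM, a share of 1), and GF271 in Low had 3 sequences at 0 against 1 in each other GF mouse (a share of 1).

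By the test of the difference, the CV minus GF log2 change in Low lay above the mean of the other sorted populations for miR-143-3p (2.07), miR-203-3p_+_1 (1.65), miR-93-5p (1.64), miR-101b-3p (1.61), miR-107-3p (1.49), miR-106b-3p (1.47), miR-203-3p (1.45), miR-21-5p (1.39), miR-30e-3p (1.31), miR-181b-2-5p (1.29), miR-181b-1-5p (1.29), miR-25-3p (1.28), miR-378-3p (1.28), miR-101b-3p_-_1 (1.16), miR-30a-3p_+_1 (1.03), miR-148a-3p (0.91) and miR-130b-3p (0.90), and below it for miR-1224-5p (-2.88). The adjustment was over the sequences tested in that comparison.

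The first pattern is the 27 calls between CV and GF mice in Low. The CV246 Low library lay nearer to the mean of Sublow (r = 0.986) than of Low (0.973). So did the Low libraries of CV304 (0.977 against 0.969) and CV314 (0.978 against 0.956). The CV246 Sublow library lay nearer to Low (0.989) than to Sublow (0.940), so an exchange of the 2 CV246 libraries is not excluded. As the source of the calls, such a mix-up is argued against for the 26 that were also called, in the same direction, without both libraries. It stays open for 1, miR-375-3p, which went from -1.40 ± 0.47 to -1.24 ± 0.44 (adjusted p from 0.042 to 0.058) with fewer libraries. A share of reads taken by other miRNAs is argued against by the 21 that both rescalings call in the same direction, while for the 6 that lose their call under 1 or both rescalings it stays open. Median-of-ratios scaling lowered the log2 of all 27 by about the shift of the median, so the drop does not set these 6 apart. It took miR-148a-3p from 0.97 ± 0.23 to 0.56 ± 0.27 and miR-802-5p from 2.24 ± 0.67 to 1.84 ± 0.71. The kept miR-25-3p went from 1.59 ± 0.25 to 1.19 ± 0.24. Quantile normalization still called miR-802-5p (2.14 ± 0.60) and miR-30a-3p_+_1 (0.82 ± 0.30), and median-of-ratios scaling miR-181b-2-5p (0.87 ± 0.25) and miR-378-3p (0.83 ± 0.28), while miR-92a-2-3p and miR-148a-3p were called under neither. More mesenchymal cells in the gate were not tested as a source of the rise of miR-143-3p, the only miRNA of its list in the table. More Sublow-type cells in the Low gate of CV mice stays open: all 27 calls move in the direction of Sublow minus Low in CR mice, 18 have a CV Low mean beyond all 4 GF population means, but 0 with each of the 4 differences past the threshold, which neither excludes nor shows a mixture. High-type cells in the GF Low gate were not tested. A response of the stem cells to 2 weeks of microbes cannot be told apart from a changed mixture. Either may account for the pattern.

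The second pattern is the isomiR ratios of CR mice: the level of the 5'-shifted form relative to its canonical form was above both CV and GF mice for 17 isomiRs of 58, such as miR-21-5p_+_1 (2.43 against CV), and below both for 0. Sequencing run or library batch would give these 17, and so would age or never having been germfree, and all of these differ together between CR mice and the others. They cannot be told apart here.

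The last pattern is that Low calls rise from 27 to 85 without the GF305 Neg library, although that library is not a Low library. Zeros of a thinly covered library that widen the spread shared by all groups could produce this, and a pseudocount of 10, which draws zeros nearer to the other values, gave 65 calls, as that explanation needs. A pseudocount of 0.1, which moves zeros further out, gave 23, within 1.5 times of 27. Since a pseudocount of 10 also narrows the spread of other low sequences, the test is not specific to this library. The 96 zeros of this library against 7 to 22 in the other GF Neg libraries go with it. Its smallest value above 0 was 41.7 RPMMM, against 2.00 to 7.17 in the other GF Neg libraries, which goes with few reads. Its depth is unknown, so a difference of the cells is not excluded, and no biological explanation was tested.

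Other splits of the samples tested whether chance groupings give as many calls. Splits of the 8 GF and CV mice, 35 in all and fitted without the litter term, argue against chance for Low. The real split gave 27 calls and any other at most 2, the smallest share that 35 splits allow. The splits that also part every pair, 8 in all, are too few for a share under 0.05 (27 against a highest other of 0). For CR against CV (28 against 2) and CR against GF (17 against 1), chance is argued against too, but run and age are not. Where the real split gave 0, all 35 splits give as many by construction, so nothing follows about chance: High (highest other 0), Sublow (1), the mean response (0, with 1 call when the litter term is kept), the F test (0), Neg (3) and NS (21). The splits with 3 in Neg and 21 in NS are those of the sequencing dates. The October NS libraries, GF305 and CV304, are both of pair C, so date and litter cannot be told apart in NS. Within dates the conventionalization counts were 0 and 1 in Neg (September and October) and 1 in September NS. October NS holds 1 GF and 1 CV library, so no count is given.

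With population labels permuted within mice in 100 splits, the real labels gave the most calls in each comparison except Sublow. A share under 0.05 argues against chance, in Sublow too (3 of 100 in GF and CV, 2 in CR). Permuting all labels tests if populations differ, not which one does. In GF and CV mice the real counts and highest others were 120 and 85 in High, 100 and 81 in Low, 157 and 73 in Neg, 115 and 69 in NS, and 36 and 51 in Sublow, where 3 splits, the real one included, gave as many. In CR mice they were 116 and 78 in High, 116 and 103 in Low, 160 and 99 in Neg, and 78 and 103 in Sublow, where 2 splits gave as many. In the others only the real split did.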

How the results depend on the processing

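Alternatives were added after the data were seen: without the GF305 Neg library, without the GF305 Low library, and without the CV246 Low and Sublow libraries. The tests with them were chosen only after the results were seen, all other alternatives were planned, and the cause of a change was not tested, except for the GF305 Neg library. The values are counts of sequences past the adjusted threshold, and those of the lists are counts of list tests past it in the comparisons named here, which leave out the response of each population against the others, where 4 passed in Low, 2 in High and 1 in Sublow. As reported they are CV-GF High 0, CV-GF Low 27, CV-GF Sublow 0, CV-GF Neg 0, CV-GF NS 0, CV-GF mean 1, F test 0, CR-CV 28, CR-GF 17, NS markers 115, lists 27, High markers 120, High markers in CR 116, Low markers 100, Low markers in CR 116, Sublow markers 36, Sublow markers in CR 78, Neg markers 157, Neg markers in CR 160.

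With the estimated correlation the lists gave 14, so many list tests rest on the preset one, and no list call changed in the fit with no replicate block. Array weights, which weigh down poorer libraries and whose estimation stopped before converging in 2 of 3 fits, gave CV-GF High 9, CV-GF Low 129, CV-GF Sublow 66, CV-GF Neg 2, CV-GF NS 50, CV-GF mean 105, F test 104, CR-CV 121, CR-GF 85, High markers 182, Sublow markers 129. The September group alone gave CV-GF NS 1, CV-GF mean 0, Sublow markers 65, and the October group alone CV-GF Low 13, CV-GF Neg 1, CV-GF mean 0, NS markers 62, High markers 71, Low markers 43, Sublow markers 1. The October CV-GF NS count is not given, since it compares 1 GF with 1 CV library. The filter of 1000 gave CV-GF mean 10, CR-CV 2, CR-GF 1, NS markers 46, High markers 46, High markers in CR 43, Low markers 43, Low markers in CR 56, Sublow markers 21, Sublow markers in CR 36, Neg markers 59, Neg markers in CR 66, with far fewer sequences tested. Median-of-ratios rescaling gave CV-GF Low 43, CV-GF NS 3, CV-GF mean 0, F test 2, Sublow markers 11, and quantile normalization CV-GF Low 82, CV-GF Sublow 1, CV-GF NS 3, CV-GF mean 54, CR-CV 58, CR-GF 46. A pseudocount of 10 gave CV-GF Low 65, CV-GF NS 6, CV-GF mean 27, F test 9, CR-GF 32, and one of 0.1 F test 2. eBayes without a trend gave CV-GF mean 4, F test 3, and sorted libraries only CV-GF mean 0, F test 3, CR-GF 28. With no replicate block the counts were CV-GF mean 6, CR-CV 49, CR-GF 36, and the separate fit with the littermate pair as block gave CV-GF Low 110. Without the GF305 Neg library they were CV-GF Low 85, CV-GF NS 11, CV-GF mean 39, F test 35, Sublow markers 64, without the GF305 Low library CV-GF Low 17, CV-GF mean 0, and without the CV246 Low and Sublow libraries CV-GF mean 12, F test 9.

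Leaving out each mouse in turn gave, from lowest to highest, CV-GF Low 20 to 50, CV-GF Neg 0 to 1, CV-GF NS 0 to 4, CV-GF mean 0 to 17, F test 0 to 26, Sublow markers 10 to 65, Sublow markers in CR 33 to 86, CR-CV 18 to 66, CR-GF 9 to 29. Apart from the October CV-GF NS count, the counts not named under a setting stayed within 1.5 times the reported one. The 27 CV-GF calls in Low had the same direction under every setting run, miR-25-3p from 1.13 to 2.03 and miR-375-3p from -1.80 to -1.23. How far depth limits these results is unknown.

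Of the 279 results for named miRNAs, the sign turned in a few. miR-127-3p among the Sublow markers went to -0.026 under quantile normalization. miR-192-5p in Neg went to 0.56 in GF and CV mice and 0.90 in CR mice under median-of-ratios rescaling, and in High of CR mice to 0.48 under quantile normalization. Under a pseudocount of 10, 272 kept their side of the threshold, 5 newly passed and 2 no longer did, and with a pseudocount of 0.1 12 no longer did. Under median-of-ratios rescaling 8 and under quantile normalization 6 no longer passed, and 36 did not in the October group alone, which holds fewer mice.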

Other observations

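The tests of cell mixture below were chosen only after the results were seen, and the tests of isomiR ratios were planned. miR-375-3p, miR-7b-5p, miR-184-3p and miR-1224-5p were high in High and GF Low and low or at 0 in Neg. In CV Low, miR-1224-5p averaged 52.3 and miR-184-3p 147 RPMMM, against 529 and 717 in GF Low. In GF Low, miR-375-3p averaged 135744 ± 44599 RPMMM (SD, n = 4), close to the 129743 ± 9442 in GF High, and in CV Low 53080.1 ± 23756. In CV Sublow it stood at 107486 in CV246 and 15538 to 23993 in the other 3 libraries. In all, 7 of 31 sorted GF and CV libraries lay nearest to the mean of another population than their own, GF244 and GF305 Low next to High, CV246, CV304 and CV314 Low next to Sublow, and GF244 and CV246 Sublow next to Low. The samples keep their labels here.

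IsomiRs did not simply follow their canonical form across populations. Of 51 ratios of isomiR to canonical form in GF and CV mice, 9 (17.6%) differed among the sorted populations, which argues against ratios that stay fixed, and 32 of 52 did in CR mice, with 7 in both sets. miR-378-3p_+_1 relative to miR-378-3p was 0.38 ± 0.06 in High and -0.34 ± 0.06 in Neg against the other populations (limma, adjusted p = 7.1e-05 and 7.1e-04), miR-92a-1-3p_+_1 was 0.51 ± 0.08 in High (adjusted p = 3.6e-05) and miR-183-5p_+_1 0.30 ± 0.07 (adjusted p = 0.0017). Across ratios, which are not independent replicates, the effects in the 45 ratios of both sets correlated at r = 0.662 in High, -0.0136 in Low, 0.0657 in Sublow and 0.504 in Neg. That conventionalization changes which 5' end is used has no support here, with 0 ratios called between CV and GF mice in the 5 populations by limma, but a smaller change is not excluded.

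A hypothesis for the Low response is that microbes expand progenitors within the Low gate, or raise proliferation of its cells, so that miR-25-3p, miR-93-5p and miR-106b-3p rise and miR-375-3p, miR-184-3p and miR-1224-5p fall together. Effects of CV minus GF in Low and Sublow minus Low in CR mice correlated at r = 0.519 across 184 sequences, not independent replicates. The test for a mixture, more Sublow-type cells in the Low gate of conventionalized mice, with 0 of the calls beyond all 4 GF populations at each adjusted threshold, leaves it open, so such cells may account for much of the change. Sorting Low by a second stem cell marker in GF and CV littermates, or measuring these miRNAs in single cells, would separate the 2 readings: a change within stem cells should persist after stricter gating, and a mixture should not.

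A second hypothesis concerns non-sorted cells, where miR-142-5p ranged from 0 to 196 RPMMM in GF libraries and from 102 to 1402 in CV libraries, while it was 3.68 in GF Low and 2.29 in CV Low, where the CD45 gate removes leukocytes. More immune cells in the epithelium after colonization may raise it. However, the count called in NS between CV and GF mice was 0 as reported and 3 with median-of-ratios rescaling or quantile normalization. A split by sequencing date, which in NS sets pair C apart, gave more calls than the real one. Counting CD45-positive cells before sorting would test it.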
